A study of Mus musculus with 9 samples.

How the data were processed

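Gene expression was measured by RNA sequencing in 9 livers of wild-type mice, 3 on a normal diet (ND), 3 on a high-fat diet (HFD) and 3 on the HFD with hyodeoxycholic acid (HFD_HDCA). The deposited files came as a pair for each library, and the groups and replicate numbers were taken from the sample titles. The labels describe separate samples and say nothing more about cages, litters, sex or days, so each p-value measures the spread between these samples. The replicate numbers were not used as a block, because the labels do not say that a number marks something shared between groups.

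Per the labels and the names of the deposited files, the authors counted reads per gene with HTSeq, and the values in these tables were whole numbers, read as raw counts with no normalization. The file names carry the word antisense, whose exact setting was not stated. The authors also gave Cufflinks gene tables, and per the file headers these hold FPKM, fragments scaled by transcript length and by the fragments mapped. The submitters' processing notes name TopHat 1.3.2, Cufflinks 2.0.2 and the mm10 build without stating the role of each. The HTSeq version and the annotation were not stated.

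The count tables held 23337 genes and 5 classes of reads assigned to no gene, which were kept out of the tests. Reads per file ran from about 24785900 to about 28809300, and reads on genes from about 16994400 to about 20509200, or 63.9 to 72.1% of the reads in a file. At this depth 3 counts, the limit allowed by a count of 0, corresponded to 0.152 to 0.182 CPM, reads scaled to library size. This floor covers counting error only, since the reads carried no molecular identifiers. Reads aligned to several places made up 17.9 ± 1.43% of the ND files, 13.6 ± 0.356% of the HFD files and 15.3 ± 0.714% of the HFD_HDCA files (SD, n = 3 each). Reads with no annotated feature made up 11.0, 10.9 and 10.4% in the same order, unaligned reads 4.11, 3.78 and 4.03%, and reads ambiguous between genes 1.53, 0.880 and 1.14%. The class for low alignment quality was 0 in all 9 files. Replicate libraries differed by more than counting error, with chi-square per degree of freedom between 11.1 and 90.8 for pairs within a group.

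Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 12587, and libraries were scaled by TMM factors. All 9 libraries entered a single model with a coefficient for each diet, and each of the 3 comparisons was tested with edgeR's quasi-likelihood F test with robust estimation. The p-values were two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. A gene was called changed at an adjusted p under 0.05. An exact permutation test of a single gene, 3 libraries against 3, cannot go below p = 0.1, so the model's pooled spread carried the tests. Levels are given as mean CPM ± SD with n = 3, and log2 fold changes with the standard error implied by the F statistic.

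The 29 gene lists, with the cell type markers among them, were written before the data were examined, as were the 3 comparisons, the tests, the rule for naming genes and most alternatives. The 28 lists with at least 5 tested members were compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation was run beside it, and p-values were adjusted over the lists of a comparison. For each list, the members past the threshold were counted after adjustment over all genes and, separately, adjusted over the list alone. The neutrophil list had too few tested members and was read only as values. Older symbols in the files were matched to current ones through RefSeq synonyms.

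Genes were named by rule. For each comparison these were the 8 with the largest rise and the 8 with the largest fall among changed genes whose libraries did not overlap between groups and whose higher group averaged at least 2 CPM. Symbols made of Gm and digits, or ending in Rik or -ps with or without digits, were left out. Locus names such as LOC622167 were kept. To these were added genes fixed beforehand (among them Ppara, Cpt1a, Cyp4a14, Fgf21, Fasn, Scd1, Cd36, Cyp7a1, Cyp8b1, Nr0b2, Cd1d1 and Glp1r) and, where a list is described, up to 4 members with its smallest p-values. Some of the genes taken by this rule are not reported here. Positions follow GRCm38.p6, the assembly of mm10, and 250 of 251 named genes had one that overlapped the locus in the deposited tables.

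The number of genes changed by HFD and changed the opposite way with HDCA was compared with the count expected from independent lists. It was also compared with 20 simulated data sets in which no gene differed and both comparisons shared the same control libraries. The pipeline was tested on simulated data with 200 planted changes per comparison. It recovered 58 to 66% of 2-fold changes and 90 to 96% of 4-fold changes, but 6 to 24% of 1.5-fold changes, with 9 or 10 false calls among 12274 to 12310 unchanged genes.

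The alternatives were a fit of only the 6 libraries compared, replicate number as a block, RLE and upper-quartile factors, DESeq2 1.42.0, no low-count filter, a filter at 1 CPM in 3 libraries, and thresholds of 2-fold or of an adjusted p of 0.1. Further alternatives were limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes at 0.5 FPKM in at least 3 libraries, the same without that filter, each of the 9 libraries left out in turn, and limma's fry for the lists. Leaving out a pair of libraries that stood apart was added after the data were seen. The FPKM tables shared 23254 genes, 5 of which were left out because the quantification had failed. Bias by GC content or gene length was not checked. Figures were drawn with matplotlib 3.10.9.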

Results

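Liver RNA was profiled in wild-type mice kept for 12 weeks, from 8 weeks of age, on ND, on a 60% HFD, or on that HFD with 0.25% hyodeoxycholic acid, a secondary bile acid. Each diet was represented by 3 livers taken in the fed state, and the series concerns hepatic steatosis, PPARα activation and invariant NKT cells. Reads assigned to genes numbered about 16994400 to 18731600 in the ND libraries, 17299300 to 20509200 in the HFD libraries and 17059100 to 17966800 in the HFD_HDCA libraries. The first 3 principal components of the log2 counts carried 30.3, 19.8 and 14.3% of the variance.

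A pair of libraries stood apart from their groups. HFD 1 differed in clock genes, with Dbp at 85.8 CPM against 2.27 and 1.41 in HFD 2 and HFD 3, and Arntl at 4.71 CPM against 41.1 and 37.6. The other libraries numbered 1 shared part of this shift. Dbp stood at 14.6 CPM in ND 1 and 10.5 in HFD_HDCA 1, against at most 3.58 in the libraries numbered 2 and 3. Arntl stood at 17.3 and 25.3 CPM in the same order, against at least 26.2. In HFD_HDCA 1 Per2 went the other way, at 3.51 CPM against 4.24 and 5.84, and Nr1d1 lay between the other HFD_HDCA libraries. HFD_HDCA 1 differed in acute phase genes, with Saa1, encoding serum amyloid A, at 3371 CPM against 23.4 and 38.0 in the other HFD_HDCA libraries, and Lcn2 at 331 against 3.66 and 4.03. Macrophage transcripts also varied within the HFD group, where Emr1, encoding the F4/80 antigen, stood at 26.5, 6.72 and 112 CPM in HFD 1, HFD 2 and HFD 3. Of all 9 libraries HFD 2 had the lowest mean scores, relative to each gene's mean over all libraries, for macrophage (-1.004), B cell (-0.93) and endothelial (-0.73) markers.

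The first comparison asked which liver genes differ between HFD and ND. Of 13 genes typical of female liver 5 rose and 1 fell, and of 19 typical of male liver 7 fell and 0 rose. The adjusted p of each list was 0.141 with an estimated correlation. Cyp2b9, a cytochrome P450 on chromosome 7 from 26173350 to 26210661, rose from 0.457 ± 0.469 to 201 ± 69.6 CPM (SD, n = 3 each), a log2 fold change of 8.72 ± 0.70 (SE) with an adjusted p of 0.00314. Its neighbour Cyp2b13 rose to 6.08 ± 3.48 CPM (SD, n = 3) against 2 reads in all ND libraries together, a ratio of 168 with a 95% Clopper-Pearson counting interval of 46.3 to 1395 and an adjusted p of 0.00672. Hao2, encoding a peroxisomal hydroxyacid oxidase, rose by 6.09 ± 0.63 on the log2 scale to 5.42 ± 1.43 CPM (SD, n = 3), a fold that rests on 0 to 3 reads per ND library. Hsd3b5, a male-typical steroid dehydrogenase, fell from 288 ± 66.8 to 76.0 ± 20.2 CPM (SD, n = 3 each, adjusted p = 0.00447).

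Among the other largest rises were Stap1, Slc22a27, Rad51l1 (now Rad51b), Themis and the hepcidin gene Hamp2, with log2 fold changes of 3.48 to 4.65 and adjusted p from 0.00403 to 0.0329. Rad51l1, on chromosome 12 from 79297282 to 79848260, rose from 0.677 ± 0.574 to 11.2 ± 3.36 CPM (SD, n = 3 each). The largest fall was that of Selenbp2, a selenium-binding protein gene on chromosome 3 from 94693573 to 94704406, from 1008 ± 590 to 34.0 ± 18.0 CPM (SD, n = 3 each, log2 fold change -4.89 ± 0.83, adjusted p = 0.0406). This call held in 2 of the 9 fits that left out a library, and its adjusted p reached 0.153 without HFD 2. Gpr110 (now Adgrf1), an adhesion receptor gene, fell from 23.6 ± 1.80 to 1.91 ± 0.882 CPM (SD, n = 3 each, log2 fold change -3.62 ± 0.29, adjusted p = 0.00165) and passed in all 9 such fits. Cyp4a12b, a fatty acid hydroxylase typical of male liver, fell by 3.89 on the log2 scale, and Mup7, a major urinary protein gene, fell by 2.88. Falls of 2.93 to 3.75 on the log2 scale were called for Cspg5, Tuba8, Slc13a2 and Acsm2, whose means lay between 0.244 and 5.82 CPM. Among these calls, 5 of the 9 fits without a library kept those of Slc22a27 and Slc13a2, 4 those of Themis and Cspg5, 3 those of Hamp2 and Cyp4a12b, and 2 those of Mup7 and Acsm2, with adjusted p up to 0.180. Cspg5 had an adjusted p of 0.0933 in the FPKM tables. Reads are shared within the Cyp2b, Cyp4a and Mup families, so the level of a single member is less certain than the level of its family.

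The sex-biased lists had the largest median shifts of the 28 lists. Of 20 genes in each, 19 male-biased and 13 female-biased passed the low-count filter. The filter keeps a gene that is high in a single diet group, such as Cyp2b13 with 2 reads in ND, which can raise a list's median. Of 19 male-biased liver genes 7 fell and 0 rose, 14 fell when adjusted over the list alone, and the list as a whole was lower (camera adjusted p = 4.45e-18, adjusted p = 0.141 with an estimated correlation, median log2 fold change -0.98). Ugt2b1 fell from 1149 ± 259 to 441 ± 80.9 CPM (SD, n = 3 each) and Keg1 fell by 0.98 on the log2 scale. Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, fell from 503 ± 177 to 96.5 ± 26.7 CPM (SD, n = 3 each, adjusted p = 0.0162). Of 13 female-biased genes 5 rose and 1 fell, with 9 and 2 adjusted over the list alone (camera adjusted p = 1e-07, adjusted p = 0.141 with an estimated correlation, median 1.95). Cyp17a1, a steroid hydroxylase, rose from 4.27 ± 0.599 to 24.2 ± 10.96 CPM (SD, n = 3 each, adjusted p = 0.0118). Both lists were called by fry (adjusted p = 0.0144 and 0.00302).

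Among lipid genes, of 23 for fatty acid synthesis 2 rose and 0 fell, and 8 rose when adjusted over the list alone (camera adjusted p = 0.000809, adjusted p = 0.762 with an estimated correlation, median 0.73). Pklr, encoding liver pyruvate kinase, rose from 112 ± 9.75 to 353 ± 143 CPM (SD, n = 3 each, adjusted p = 0.0231), and Dak (now Tkfc), a kinase of fructose metabolism, rose by 1.04 on the log2 scale. Fasn, encoding fatty acid synthase, was at 747 ± 562 CPM in HFD against 231 ± 22.5 in ND (SD, n = 3 each, adjusted p = 0.180). The list's mean score, the log2 CPM of its members relative to their mean over all libraries, was -0.11, 0.45 and 1.41 in HFD 1, HFD 2 and HFD 3. Its call ended without HFD 3 (adjusted p = 0.301). Without HFD 1, the library apart in clock genes, 6 of its members rose. Of 23 tested genes of lipid droplets and lipid uptake 1 rose and 0 fell, with 9 and 1 adjusted over the list alone (camera adjusted p = 8.76e-06, adjusted p = 0.351 with an estimated correlation). The member that rose was Fabp2, a fatty acid binding protein gene, from 68.7 ± 7.74 to 220 ± 41.2 CPM (SD, n = 3 each, adjusted p = 0.0106). Apoa4 was at 929 ± 734 against 64.0 ± 7.02 CPM (SD, n = 3 each, adjusted p = 0.0662). Without HFD 1, 4 members of the droplet list rose.

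Genes of fatty acid β-oxidation were higher as a list (1 of 25 rose, 0 fell, 2 rose adjusted over the list alone, camera adjusted p = 0.00184, adjusted p = 0.762 with an estimated correlation). The call ended without HFD 2 (adjusted p = 0.287). For the 25 PPARA targets edgeR called 0 members in either direction, although 6 lay above and 2 below at an unadjusted p under 0.05 and DESeq2 called 3 up and 2 down. Adjusted over the list alone 3 rose and 2 fell, and the list's camera adjusted p was 0.0530 (adjusted p = 0.937 with an estimated correlation). It passed without any 1 of ND 2, HFD 1, HFD 3 or the 3 HFD_HDCA libraries and reached 0.000440 without ND 2. Angptl4 was at 81.0 ± 23.5 against 247 ± 59.1 CPM and Acot3 at 26.5 ± 4.05 against 4.99 ± 3.69 (SD, n = 3 each), with adjusted p of 0.0592 and 0.0702. Of the genes fixed beforehand, Ppara, Cpt1a, Cyp4a14, Fgf21, Scd1, Cyp7a1, Cyp8b1, Nr0b2 and Cd1d1 had adjusted p from 0.271 to 0.945 in this comparison. The fatty acid translocase gene Cd36 was at 188 ± 25.8 against 74.1 ± 15.6 CPM (SD, n = 3 each, adjusted p = 0.200).

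In the other called lists edgeR passed 0 members at the adjusted threshold. Interferon response genes were higher (26 of 28 positive, median 0.39, camera adjusted p = 1.6e-07, 0.375 with an estimated correlation), with 8 up and 1 down adjusted over the list alone. At an unadjusted p under 0.05 11 of them lay above and 1 below, and DESeq2 called 4 up. Liver endothelial markers were lower (16 of 17 negative, median -0.38, camera adjusted p = 9.06e-06, 0.762 with an estimated correlation), with 3 below at an unadjusted p under 0.05 and 0 called by DESeq2. They were lowest in HFD 2, with a mean score of -0.73 against 0.02 and 0.24 in HFD 1 and HFD 3. NRF2 and glutathione genes were lower (camera adjusted p = 0.000387, 0.581 with an estimated correlation), with 1 up and 6 down adjusted over the list alone, 10 below at an unadjusted p under 0.05 and 6 called lower by DESeq2. Gstp1 was at 158 ± 14.5 against 588 ± 78.5 CPM (SD, n = 3 each, adjusted p = 0.0588). This call ended without both libraries that stood apart (adjusted p = 0.0584). Cell cycle genes were higher (22 of 23 positive, camera adjusted p = 0.00184) and periportal hepatocyte genes lower (camera adjusted p = 0.0115), each with an adjusted p of 0.762 with an estimated correlation. DESeq2 called 0 cell cycle genes, against 5 above at an unadjusted p under 0.05, and 1 periportal gene each way, the same as adjusted over the list alone, where 0 cell cycle and 0 endothelial genes passed. The cell cycle call ended without ND 3 (0.0627) or HFD 3 (0.134), and the periportal call without ND 1 (0.0600) or HFD 3 (0.130).

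The remaining lists were not called. Bile acid synthesis and transport genes lay lower (0 rose, 1 fell, 0 and 3 adjusted over the list alone, adjusted p = 0.0551), as did CAR and PXR xenobiotic genes (2 rose, 3 fell, 5 and 10 adjusted over the list alone, adjusted p = 0.0728). The mean of the CAR and PXR list was positive at 0.19, and its rises were those of Cyp2b9 and Cyp2b13, shared with the female-biased list. In the CAR and PXR list Cyp3a11, the main cytochrome of bile acid and drug hydroxylation, fell from 5306 ± 960 to 951 ± 217 CPM (SD, n = 3 each, adjusted p = 0.0232). Leaving out HFD 2 brought both lists past the threshold (0.0131 and 0.0115), and leaving out HFD_HDCA 1 the CAR and PXR list (0.0261), of which 2 members then rose and 8 fell. Glucose genes (adjusted p = 0.415) held 1 that rose, the fructokinase gene Khk, and 1 that fell, Foxo1, with 7 and 4 adjusted over the list alone, and without HFD 1 3 rose and 5 fell. Pericentral genes (0.970) held 1 that fell, Cyp1a2 (2 up and 2 down adjusted over the list alone), and clock genes (0.369) 1 that rose, Wee1 (2 up). The adjusted p was 0.567 for cholesterol synthesis, 0.317 for inflammatory cytokines, 0.970 for acute phase, 0.415 for fibrosis, ER stress and oxidative phosphorylation, and 0.675 for macrophages and cholangiocytes. It was 0.784 for T, NK and NKT cells, 0.496 for B cells, 0.567 for immediate early genes and 0.771 for transcripts of other tissues. Medians were positive where the test pointed down for cholesterol synthesis (0.07), acute phase (0.09), macrophages (0.12), B cells (0.05) and other tissues (0.05). The cholesterol list became lower without HFD 3 (2.59e-08), the fibrosis list higher without HFD 1 (0.0128), the inflammatory list higher without HFD 2 (0.00439), and the macrophage list higher without HFD 2 (0.00767) and lower without HFD 3 (0.00763).

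In total 120 of 12587 genes changed between HFD and ND, 60 in each direction, with a median fold of 2.83 among them. For all 120 every library of one group lay above every library of the other, which held for 20.1% of all genes tested and holds for 10% by chance. The count depended on single libraries, falling to 36, 44 and 32 without ND 1, ND 2 and ND 3 and to 40 and 34 without HFD 2 and HFD 3. It stood at 226 without HFD 1 and 208 without HFD_HDCA 1, and the FPKM tables gave 108 up and 66 down. Of the list members named, Pklr, Foxo1, Wee1, Cyp1a2 and Cyp3a11 passed in 4 of the 9 fits without a library, Khk in 3 and Dak in 2. In the FPKM tables Foxo1 and Wee1 had adjusted p of 0.0864 and 0.0528.

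The next comparison asked what HDCA changed on the HFD background. Fatty acid synthesis genes were lower with HDCA as a list, with 5 of 23 that fell (adjusted p = 0.531 with an estimated correlation). Srebf1, encoding the lipogenic transcription factor SREBP1, on chromosome 11 from 60199084 to 60224186, fell from 400 ± 60.9 to 68.8 ± 23.5 CPM (SD, n = 3 each, adjusted p = 0.00283). Thrsp, a lipogenic regulator on chromosome 7 from 97412933 to 97417550, fell from 235 ± 75.02 to 21.7 ± 7.06 CPM (SD, n = 3 each, adjusted p = 0.00625). Cyp4a31 and Cyp4a10, fatty acid ω-hydroxylases and PPARα targets on chromosome 4, rose from 8.24 ± 2.95 to 72.2 ± 4.60 CPM and from 395 ± 205 to 2078 ± 670 CPM (SD, n = 3 each).

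Of the 23 fatty acid synthesis genes 5 fell and 0 rose, 13 fell when adjusted over the list alone, and 22 of 23 lay lower (camera adjusted p = 9.73e-09, adjusted p = 0.531 with an estimated correlation, median log2 fold change -1.19). Besides Srebf1 and Thrsp, Fasn, on chromosome 11 from 120805958 to 120825166, fell from 747 ± 562 to 104 ± 25.3 CPM (SD, n = 3 each, log2 fold change -2.84 ± 0.49, adjusted p = 0.0220). Pklr fell by 1.71 on the log2 scale. Fasn missed the threshold in 2 of the 9 fits without a library, reaching 0.0863 without HFD_HDCA 3. Scd1, encoding stearoyl-CoA desaturase, was at 2282 ± 1995 against 6898 ± 4808 CPM (SD, n = 3 each, adjusted p = 0.230). The list remained lower without any single library (adjusted p at most 5.28e-07) and held 11 members that fell without HFD 1 and 4 without HFD_HDCA 1.

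Of the 25 PPARA targets 6 rose and 0 fell, 19 rose when adjusted over the list alone, and all 25 lay higher (camera adjusted p = 1.09e-10, adjusted p = 0.531 with an estimated correlation, median 1.34). Cyp4a31 rose by 3.13 ± 0.47 on the log2 scale (SE, adjusted p = 0.0142) and Cyp4a10 by 2.39 ± 0.52 (SE, adjusted p = 0.0469). The rise of Cyp4a10 was past the threshold in 1 of the 9 fits without a library and at 0.148 without HFD 3. Cyp4a32 rose from 26.8 ± 5.12 to 79.1 ± 2.03 CPM and the fatty acid transporter gene Slc27a1 from 7.01 ± 2.65 to 24.6 ± 5.66 CPM (SD, n = 3 each, adjusted p = 0.00283 and 0.00872). Both passed in all 9 such fits. The FPKM tables gave the same calls for Cyp4a10, Cyp4a31 and Cyp4a32, members of a family that shares reads. Cyp4a14 was at 5292 ± 2034 against 989 ± 320 CPM (SD, n = 3 each, adjusted p = 0.108) and Cpt1a at 712 ± 76.0 against 532 ± 64.4 (adjusted p = 0.162). Fgf21 was at 33.6 ± 28.7 against 7.15 ± 4.52 CPM (SD, n = 3 each, adjusted p = 0.245) and Ppara itself at 497 ± 159 against 397 ± 30.1 (adjusted p = 0.393). The list's mean score was 0.26 in HFD_HDCA 1, the library with raised acute phase genes, against 1.21 and 1.43 in the others, and 14 members rose without that library but 4 without HFD 1. The list stayed higher without any single library (adjusted p at most 1.52e-06).

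**Figure D1:**
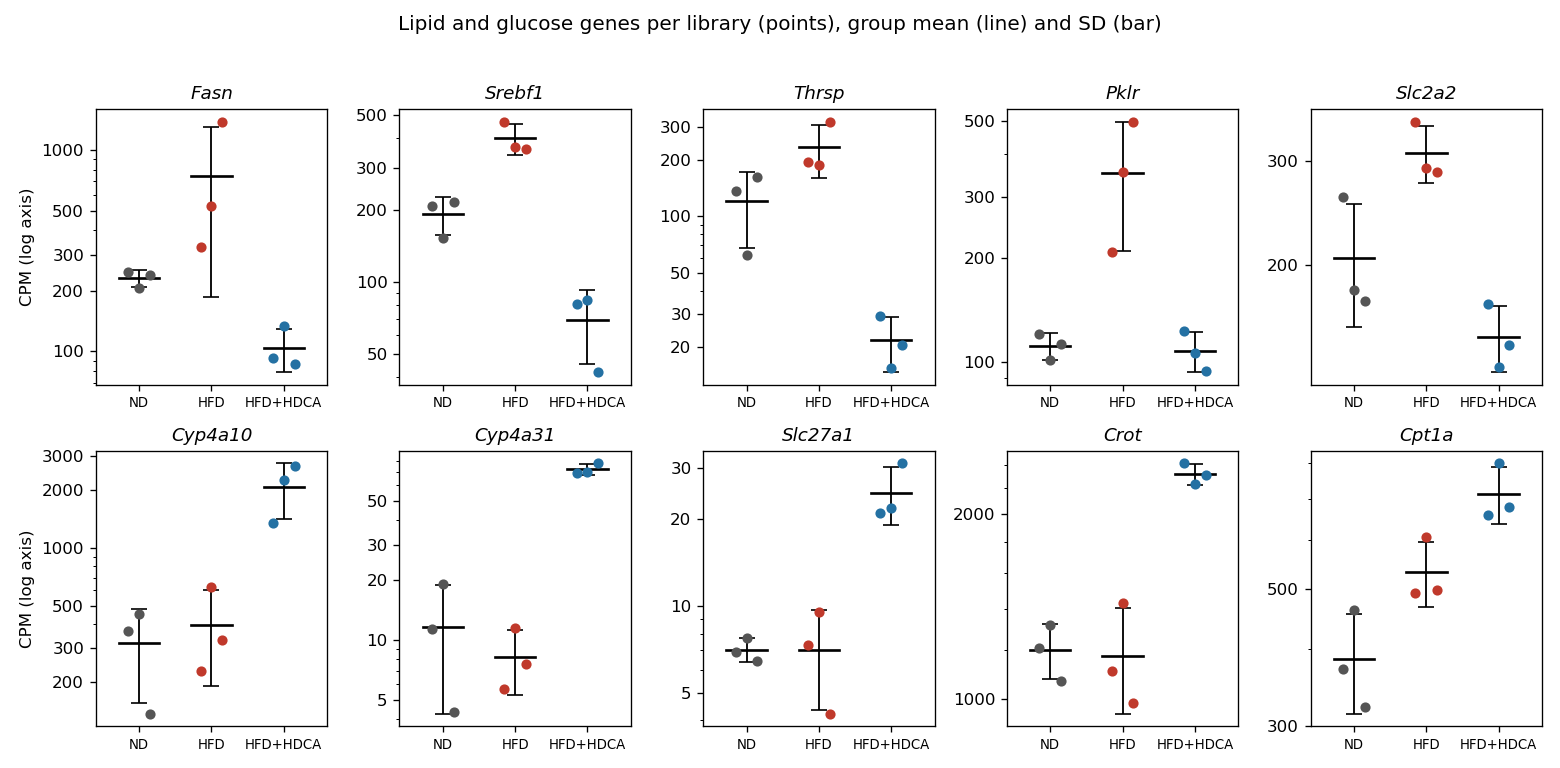
Expression of 10 lipid and glucose genes in CPM on a log axis for ND, HFD and HFD_HDCA livers, with each point a library, the line the group mean and the bar the SD. Srebf1 and Thrsp were lowest in the HFD_HDCA libraries, at means of 68.8 and 21.7 CPM, while Cyp4a10, Cyp4a31 and Slc27a1 were highest there.

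Fatty acid β-oxidation genes were higher as a list (4 of 25 rose, 1 fell, 8 and 1 adjusted over the list alone, camera adjusted p = 6.32e-05, adjusted p = 0.531 with an estimated correlation). Crot, a peroxisomal carnitine acyltransferase gene, rose from 1176 ± 230 to 2319 ± 92.1 CPM (SD, n = 3 each, adjusted p = 0.0120). Eci2 and Hadhb rose by 0.87 and 0.69 on the log2 scale. Slc25a20, the mitochondrial carnitine carrier gene counted with the PPARA targets, rose by 0.71 on the log2 scale (adjusted p = 0.0280). Oxidative phosphorylation genes were higher with 0 of 33 passing in edgeR (median 0.22, camera adjusted p = 0.0323, 0.878 with an estimated correlation), 8 above and 2 below at an unadjusted p under 0.05 and 0 called by DESeq2. That call ended without HFD 3 (0.218), HFD_HDCA 1 (0.309) or HFD_HDCA 3 (0.0797).

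Interferon response genes were higher with HDCA, where 5 of 28 rose, 0 fell and 18 rose when adjusted over the list alone (camera adjusted p = 6.54e-09, 0.531 with an estimated correlation). Ifit1, an interferon-induced antiviral gene on chromosome 19 from 34640889 to 34650009, rose from 9.53 ± 3.15 to 20.4 ± 3.04 CPM (SD, n = 3 each, adjusted p = 0.0349). Zbp1, Mx1 and Isg15 rose by 1.31, 1.11 and 0.76 on the log2 scale. Counts of members that rose were 2 without HFD 1 and 3 without HFD_HDCA 1. T, NK and NKT cell markers (11 of 12 positive, median 0.40, camera adjusted p = 0.0170) and B cell markers (7 of 7 positive, median 0.94, camera adjusted p = 0.00262) lay higher, both at 0.531 with an estimated correlation. Only 12 of the 29 T, NK and NKT markers in the counts, and 7 of the 12 B cell markers, had enough reads to be tested. The former include Cd1d1, which does not mark these cells. The B cell score was -0.93 in HFD 2 against -0.01 and 0.00 in HFD 1 and HFD 3, and without HFD 2 the adjusted p of that list was 0.0470. In these lists edgeR passed 0 members, 2 and 4 were above at an unadjusted p under 0.05, and DESeq2 called 0. Without both libraries that stood apart the T, NK and NKT list ended at 0.0534, although its median was then 0.59. Cd1d1, which encodes the antigen-presenting molecule of NKT cells, was at 280 ± 36.8 against 219 ± 19.3 CPM (SD, n = 3 each, adjusted p = 0.142). The GLP-1 receptor gene Glp1r had 0 reads in 8 libraries and 1 read in HFD_HDCA 1, so a difference was not detectable at this depth.

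Pericentral hepatocyte genes were lower, with 5 of 19 falling, 0 rising and 11 falling when adjusted over the list alone (camera adjusted p = 8.79e-06, 0.531 with an estimated correlation). Nkd1, an inhibitor of Wnt signalling, fell from 10.3 ± 0.503 to 5.06 ± 0.406 CPM (SD, n = 3 each, adjusted p = 0.0152), and Cyp1a2, Rgn and Slc1a4 fell by 0.82, 0.72 and 1.98 on the log2 scale. CAR and PXR genes were lower (1 of 24 rose, 4 fell, 1 and 6 adjusted over the list alone, camera adjusted p = 0.0323, 0.681 with an estimated correlation), among them Cyp2c29, Abcb1a and Aldh1a7. That call ended without HFD 1 (0.0613), HFD 2 (0.140) or HFD_HDCA 2 (0.156). Without HFD 1 the list's median was nevertheless -0.54, against -0.39 with all libraries. Cell cycle genes were lower (2 of 23 fell, 0 rose, 3 fell adjusted over the list alone, camera adjusted p = 0.00257, 0.686 with an estimated correlation), with Rrm2 and Ccnd1 falling by 1.35 and 1.48 on the log2 scale. That call ended without HFD_HDCA 2 (0.0906), while 5 members fell without HFD 1, 1 without HFD_HDCA 1 and 6 without both. Fibrosis and stellate cell genes were lower (camera adjusted p = 0.0455, 0.686 with an estimated correlation) with edgeR passing 0, 3 below at an unadjusted p under 0.05 and 1 called by DESeq2. Their adjusted p ran from 0.0552 to 0.394 in 7 of the 9 fits without a library, the exceptions being HFD 1 and HFD_HDCA 1. The fibrosis genes that fell were 3 without HFD 1, 0 without HFD_HDCA 1 and 9 without both.

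Male-biased genes were higher as a list, with 3 of 19 rising, 0 falling and 10 rising when adjusted over the list alone (camera adjusted p = 6.32e-05, 0.531 with an estimated correlation). Mup21 rose from 375 ± 51.4 to 918 ± 136 CPM, Mup3 from 8236 ± 1039 to 15395 ± 1843 and Cyp7b1 from 96.5 ± 26.7 to 305 ± 109 (SD, n = 3 each, adjusted p = 0.00380, 0.0118 and 0.0290). The FPKM tables gave the same direction for all 3. Of these Cyp7b1 had fallen with HFD, while Mup21 and Mup3 had not passed between HFD and ND (adjusted p = 0.503 and 0.763). The list's mean score was 0.21, 0.03 and -0.46 in HFD_HDCA 1, HFD_HDCA 2 and HFD_HDCA 3, against -1.12, -0.49 and -0.46 in the HFD libraries. Without both libraries that stood apart the list ended at 0.0534. The female-biased list was not called (1 rose, 2 fell, 2 and 2 adjusted over the list alone, adjusted p = 0.782). Even so, Cyp2b13 and Hao2 fell by 4.42 and 3.08 on the log2 scale, with 1 to 10 reads of Cyp2b13 per HFD_HDCA library.

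Other named falls were those of Cyp26a1, a retinoic acid hydroxylase gene, Themis, Lrtm1 and LOC622167, with log2 fold changes of -3.26, -4.12, -3.14 and -3.92. Other named rises were Csad, the decarboxylase of taurine synthesis, from 75.6 ± 19.6 to 381 ± 160 CPM, Enho, encoding adropin, from 7.26 ± 1.20 to 40.7 ± 24.99, and the leptin receptor gene Lepr from 3.15 ± 0.873 to 14.2 ± 7.22 (SD, n = 3 each, adjusted p = 0.0196, 0.0255 and 0.0283). Peg3, Bik and Cspg5 rose by 2.32, 2.19 and 3.86 on the log2 scale. Among bile acid genes (1 rose, 2 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.795) Abcb11, the bile salt export pump gene, fell from 711 ± 20.4 to 363 ± 63.5 CPM (SD, n = 3 each, adjusted p = 0.00825). Fgfr4 fell by 0.63 on the log2 scale. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, was at 21.1 ± 23.8 against 77.4 ± 46.0 CPM, and Cyp8b1 at 827 ± 50.8 against 401 ± 208 (SD, n = 3 each, adjusted p = 0.252 and 0.148). Cd36 and Nr0b2 had adjusted p of 0.537 and 0.487.

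Of the uncalled lists, glucose metabolism (0 rose, 3 fell, 2 and 5 adjusted over the list alone, adjusted p = 0.115) held falls of Slc2a2 and Pygl among others, and passed without HFD 2 (0.0470). Droplet genes (0.782) held a rise of Fitm2 and a fall of Dgat2, and clock genes (0.167) falls of Per2 and Bhlhe40. NRF2 genes (0.0634) held falls of Gstm6 and Ces2g, inflammatory genes (0.0634) a rise of Il1rn and ER stress genes (0.222) a rise of Sesn2. Adjusted over the list alone, 4 droplet genes rose and 2 fell, 2 clock genes fell, 1 NRF2 gene rose and 5 fell, and 1 inflammatory and 1 ER stress gene rose. Acute phase genes (0.191) held a rise of Lbp and a fall of Steap4, with a median of 0.65 that became -0.12 without HFD_HDCA 1. The adjusted p was 0.619 for cholesterol synthesis, 0.0882 for macrophages, 0.578 for endothelial cells, 0.967 for cholangiocytes, 0.215 for periportal hepatocytes, 0.911 for immediate early genes and 0.729 for transcripts of other tissues. Median and test differed in sign for bile acid genes (0.03), endothelial cells (-0.06) and immediate early genes (0.13), and mean and test for cholangiocytes (-0.02). Single libraries turned or made several of these calls, as with cholesterol synthesis, lower without HFD 1 (0.0134) and higher without HFD 3 (0.00349). Macrophage markers were higher without HFD 3 (9.2e-05) or HFD_HDCA 3 (0.0119), and endothelial markers lower without HFD 2 (0.0470) and higher without HFD 3 (0.0128). Inflammatory genes were higher without HFD 1 (0.0336) or HFD 3 (0.00501), NRF2 genes lower without HFD 1 (0.0181) or HFD_HDCA 1 (0.00726), and periportal genes lower without HFD_HDCA 1 (0.00726). Without HFD 3, ER stress genes were higher (0.0289) and clock genes lower (0.0318), and acute phase genes were higher without HFD_HDCA 2 (0.0250) or HFD_HDCA 3 (0.0260).

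**Figure D2:**
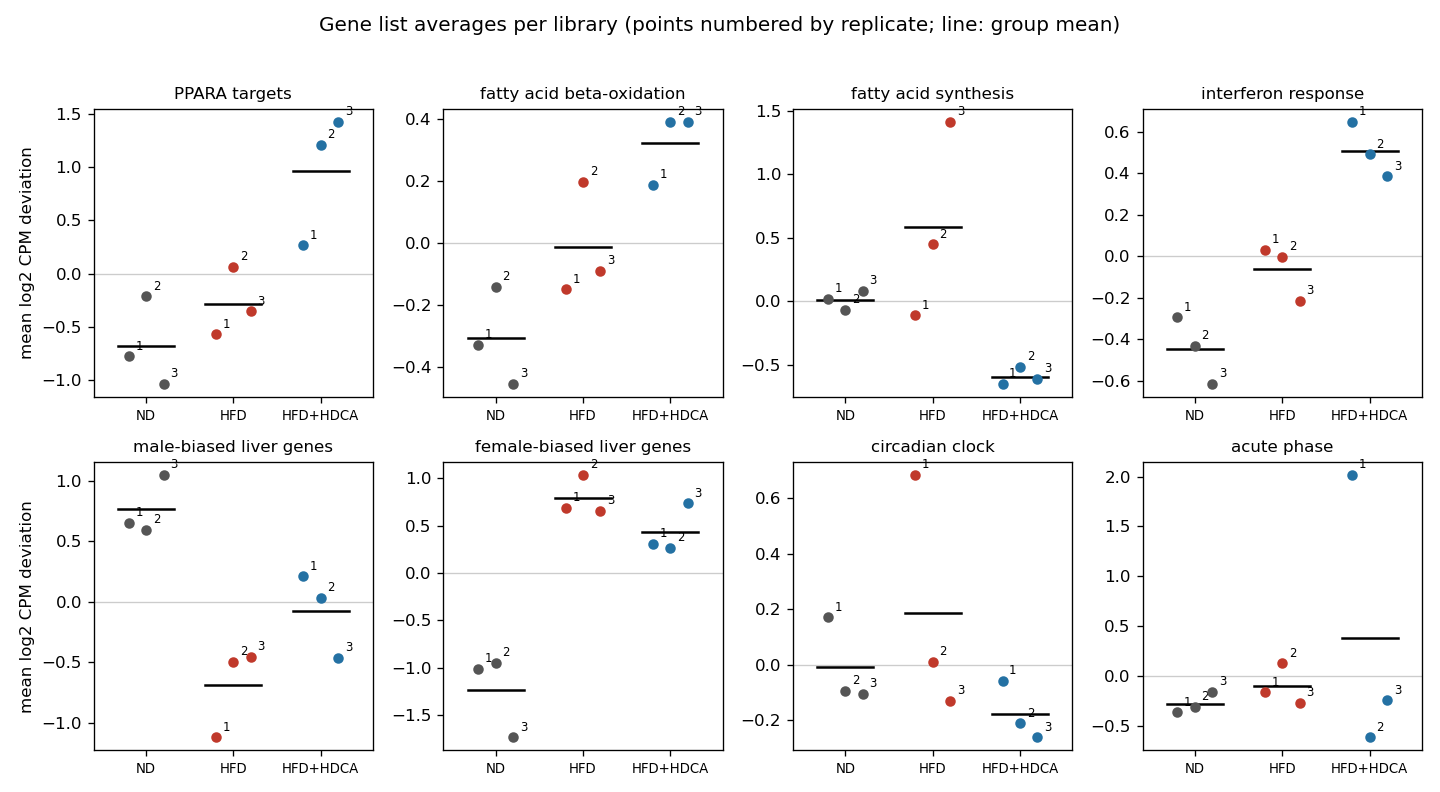
Mean log2 CPM of 8 gene lists in each library, as the deviation of each member from its mean over all 9 libraries, with points numbered by replicate and a line at each group mean. PPARA targets stood at 0.26, 1.21 and 1.43 in the HFD_HDCA libraries, and fatty acid synthesis genes at -0.65, -0.52 and -0.61.

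In this comparison 428 genes changed, 210 up and 218 down, with a median fold of 1.83. For all 428 the libraries of both groups were fully separated, against 22.4% of all genes tested and 10% by chance. The count was 217 and 242 without ND 1 and ND 2, 672, 199 and 153 without HFD 1, HFD 2 and HFD 3, and 647 and 127 without HFD_HDCA 2 and HFD_HDCA 3. Without HFD_HDCA 2 the balance was 477 up and 170 down, with FPKM it was 143 up and 381 down, and the fit of only the 6 libraries called 134. Of the genes named, Fitm2, Slc1a4, Abcb1a and Aldh1a7 passed in 1 of the 9 fits without a library, and Lrtm1, Hadhb, Dgat2, Mx1, Isg15, Rgn, Ces2g, Rrm2 and Ccnd1 in 2. Ifit1 and Cyp1a2 passed in 3, and Fgfr4, Pygl, Il1rn, Zbp1 and Bhlhe40 in 4. The FPKM tables gave adjusted p of 0.0517 to 0.165 for Cspg5, Zbp1, Hadhb, Lepr, Fitm2 and Abcb1a.

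Part of the HFD changes had the opposite sign with HDCA. Of the 120 genes changed by HFD 40 were also changed by HDCA, 35 in the opposite direction (22 up then down, 13 down then up) and 5 in the same one. Independent lists would share 1.04 genes up then down and 1.001 down then up, and simulated data without any change, in which the HFD libraries served both comparisons, gave at most 1 opposed gene. The simulated count leaves out real effects and the expected one the shared libraries, so the excess over either was not taken as a shared effect. Among the 35 were Pklr, Hao2, Cyp2b13, Themis and Dak, which rose with HFD and fell with HDCA, and Cspg5, Tuba8, Csad and Cyp7b1, which fell with HFD and rose with HDCA. Csad, on chromosome 15 from 102176997 to 102205052, was at 75.6 ± 19.6 CPM in HFD after a fall of 2.54 on the log2 scale from ND. Across all genes the covariance of both log2 fold changes was -0.0533 against -0.0405 to -0.0346 in the simulations. The simulations drew each gene independently, whereas genes were correlated in the real libraries (0.644 within the PPARA list). Such correlation would widen the simulated range, so the range does not measure chance here. The correlation of both log2 fold changes was -0.302 against -0.493 in the simulations, and signs were opposite for 57.1% of all genes against 66.6%. The HFD libraries were not divided between the comparisons, so their use in both was not separated from the excess in count and covariance. In the HFD_HDCA livers 28 of the 60 genes raised by HFD and 37 of the 60 lowered were still changed in the same direction against ND. The ND libraries enter both comparisons with the same sign, which by itself favours the same direction. No expected count was computed for this. The count of 35 ran from 7 without HFD 3, 8 without HFD 2, 10 without ND 2 and 11 without ND 1 or ND 3 to 77 without HFD 1, and was 22 without HFD_HDCA 3.

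**Figure D3:**
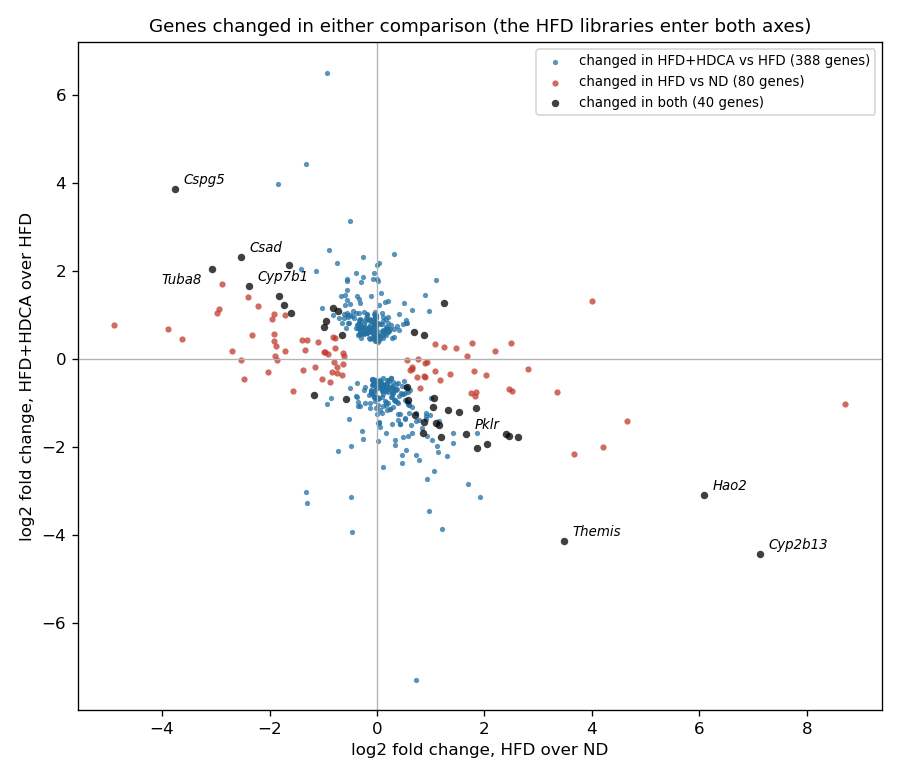
Log2 fold change of HFD over ND on the horizontal axis against HFD_HDCA over HFD on the vertical axis, each point a gene changed in either comparison. There were 80 genes changed only against ND, 388 changed only with HDCA and 40 changed in both, 35 of which have opposite signs on the axes.

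The last comparison set HFD_HDCA against ND and so asked how far livers on both differ from controls. The PPARA, β-oxidation and interferon lists were higher than in ND, with 14 of 25, 11 of 25 and 19 of 28 members that rose. Their adjusted p was 0.430, 0.430 and 0.299 with an estimated correlation. Acot3, encoding a peroxisomal acyl-CoA thioesterase, rose from 4.99 ± 3.69 to 102 ± 34.9 CPM (SD, n = 3 each, log2 fold change 4.35 ± 0.50, adjusted p = 0.00361). Cyp4a14 rose from 524 ± 470 to 5292 ± 2034 CPM (SD, n = 3 each, adjusted p = 0.0395). Cpt1a, the gene of the rate-controlling carnitine palmitoyltransferase, rose from 385 ± 70.9 to 712 ± 76.0 CPM and Cd1d1 from 193 ± 11.4 to 280 ± 36.8 (SD, n = 3 each, adjusted p = 0.0121 and 0.0340). Cyp26a1, on chromosome 19 from 37697738 to 37701536, fell from 23.002 ± 1.57 to 0.964 ± 0.634 CPM (SD, n = 3 each, log2 fold change -4.56 ± 0.38, adjusted p = 0.000764). Without ND 1 the adjusted p was 0.150 for Cyp4a14, 0.0713 for Cpt1a and 0.152 for Cd1d1.

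Of the 25 PPARA targets 14 rose and 0 fell, 21 rose when adjusted over the list alone (camera adjusted p = 2.12e-12, adjusted p = 0.430 with an estimated correlation), while 20 rose without HFD_HDCA 1, 13 without HFD 1 and 22 without both. Of 25 β-oxidation genes 11 rose and 0 fell, with 16 and 1 adjusted over the list alone (camera adjusted p = 3.47e-08, adjusted p = 0.430 with an estimated correlation), including Hadh, Hadhb, Crot and Decr2 with rises of 0.81 to 0.95 on the log2 scale. Of 23 droplet genes 7 rose and 0 fell, 9 rose adjusted over the list alone (camera adjusted p = 0.000788, adjusted p = 0.430 with an estimated correlation), among them Apoa4 with a rise of 3.95 on the log2 scale, Fabp2 and Hsd17b13. Fatty acid synthesis genes were lower than in ND as well, with 3 of 23 falling, 0 rising and 3 falling adjusted over the list alone (camera adjusted p = 0.00223, 0.584 with an estimated correlation). The members that fell were Srebf1, Thrsp and Lpin1, the last from 118 ± 31.0 to 19.0 ± 0.0997 CPM (SD, n = 3 each, adjusted p = 0.00898). Fasn was at 104 ± 25.3 against 231 ± 22.5 (SD, n = 3 each, adjusted p = 0.160). Without HFD 1, 2 members of the synthesis list rose and 4 fell.

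Of 28 interferon response genes 19 rose and 0 fell, 25 rose when adjusted over the list alone, and all 28 lay higher (camera adjusted p = 4.04e-15, 0.299 with an estimated correlation, fry adjusted p = 0.00233). Ifit1 rose from 4.83 ± 1.05 to 20.4 ± 3.04 CPM (SD, n = 3 each, adjusted p = 0.00194), and Mx1, Ifit3 and Irf9 rose by 1.76, 1.28 and 0.83 on the log2 scale. Inflammatory genes were higher (3 of 22 rose, 0 fell, 6 rose adjusted over the list alone, camera adjusted p = 0.0169, 0.509 with an estimated correlation), namely Il1rn, Cxcl10 and Ccr2, and the call ended without HFD_HDCA 1 (0.0875). B cell markers were higher (camera adjusted p = 0.0446, 0.534 with an estimated correlation) with edgeR passing 0 of 7, 3 above at an unadjusted p under 0.05, 2 up adjusted over the list alone and 0 called by DESeq2. The call ended without ND 3 (0.0742) or HFD_HDCA 2 (0.0620). The T, NK and NKT list (1 of 12 rose, Cd1d1, with 2 up and 1 down adjusted over the list alone, adjusted p = 0.0551) passed in 7 of the 9 fits without a library, the exceptions being HFD_HDCA 1 and HFD_HDCA 2. Cd1d1, at 183 to 321 CPM in every library, encodes a molecule that presents antigen to NKT cells and does not mark those cells, whereas the T cell gene Cd3e was at most 0.782 CPM.

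Pericentral genes held 4 falls among 19 and 0 rises (9 falls adjusted over the list alone, camera adjusted p = 0.000125, 0.430 with an estimated correlation). Cyp1a2 fell from 713 ± 9.47 to 180 ± 35.0 CPM (SD, n = 3 each, adjusted p = 0.000764). Periportal genes held 2 falls and 0 rises (2 rises and 5 falls adjusted over the list alone, camera adjusted p = 0.00332, 0.509 with an estimated correlation), those of the urea cycle gene Cps1 and of Cyp2f2, and 5 fell without HFD_HDCA 1. NRF2 and glutathione genes held 6 falls and 0 rises (1 rise and 8 falls adjusted over the list alone, camera adjusted p = 0.000125, 0.430 with an estimated correlation). CAR and PXR genes held 4 rises and 9 falls (4 and 11 adjusted over the list alone, camera adjusted p = 0.00533, 0.509 with an estimated correlation). Among these Gstm1, Gstm6 and Cyp3a11 fell by 1.38, 1.15 and 2.93 on the log2 scale, and Gsta2 and Cyp2c55 fell by 3.28 and 4.30. Cyp2c40 fell by 3.52 on the log2 scale in the counts but had an adjusted p of 0.166 in the FPKM tables, in a family whose members share reads. Endothelial markers were lower (15 of 17 negative, camera adjusted p = 0.00994, 0.766 with an estimated correlation) with edgeR passing 0, 1 above and 5 below at an unadjusted p under 0.05 and 0 called by DESeq2. The list ended at 0.0615 without both libraries that stood apart.

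Both sex-biased lists were called in the same direction as with HFD alone, in comparisons that share the ND libraries. Of 19 male-biased genes 2 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00242, 0.509 with an estimated correlation). Of 13 female-biased genes 6 rose and 2 fell, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.000129, 0.299 with an estimated correlation). Cyp2b9 was at 99.0 ± 43.7 CPM (SD, n = 3, adjusted p = 0.00146 against ND), and Rad51l1 rose by 5.33 on the log2 scale. Ugt2b1 and Hsd3b5 fell by 1.62 and 1.35 on the log2 scale, whereas Mup21 and Mup3 rose by 0.97 and 0.76. Acot3 belongs to the PPARA and female-biased lists alike. Further named changes were rises of Ly6d, Cgref1 and G0s2, an inhibitor of the lipase ATGL, and falls of Clec2h, LOC622167, Selenbp2 and Ccrn4l (now Noct, encoding nocturnin), with adjusted p from 0.00279 to 0.0380. The glucose list was not called (0 rose, 4 fell, 4 and 5 adjusted over the list alone, adjusted p = 0.513).

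Bile acid genes were not called (1 rose, 4 fell, 4 and 5 adjusted over the list alone, adjusted p = 0.112) but passed without HFD_HDCA 1 (0.0205). Cyp2c70, which makes muricholic acids, fell from 853 ± 343 to 98.3 ± 43.8 CPM and Abcb11 from 908 ± 48.9 to 363 ± 63.5, and Nr1h4, encoding the bile acid receptor FXR, rose from 103 ± 14.8 to 169 ± 12.6 (SD, n = 3 each, adjusted p = 0.00421, 0.00146 and 0.0202). Cyp8b1 was at 827 ± 50.8 against 316 ± 53.1 CPM and Fgf21 at 33.6 ± 28.7 against 1.33 ± 1.47 (SD, n = 3 each), with adjusted p of 0.0630 and 0.0614. Ppara, Scd1, Cd36, Cyp7a1 and Nr0b2 had adjusted p from 0.0981 to 0.383. The adjusted p was 0.300 for cholesterol synthesis and fibrosis, 0.260 for acute phase, 0.218 for macrophages, 0.627 for cholangiocytes, 0.607 for ER stress, 0.618 for clock genes, 0.206 for oxidative phosphorylation, 0.562 for the cell cycle, 0.475 for immediate early genes and 0.472 for transcripts of other tissues. Medians were positive against a test that pointed down for fibrosis (0.08), clock (0.02) and cell cycle (0.02), and for other tissues the mean was (0.08). Fibrosis and cell cycle genes were lower without HFD_HDCA 1 (0.0149 and 0.0148), acute phase genes higher without HFD_HDCA 2 (0.0334) or HFD_HDCA 3 (0.0390), oxidative phosphorylation higher without HFD_HDCA 2 (0.00190) and macrophages higher without HFD_HDCA 3 (0.0233).

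Against ND 815 genes changed, 460 up and 355 down, with a median fold of 1.79. The libraries were fully separated for 814 of them, against 33.9% of all genes tested and 10% by chance. The count was 196, 344 and 332 without ND 1, ND 2 and ND 3, and 308 without HFD_HDCA 3. Of the genes named, Cyp4a14 passed in 2 of the 9 fits without a library, Ccrn4l and Ccr2 in 3, and Cd1d1 in 4. In the FPKM tables Ccrn4l and Ccr2 had adjusted p of 0.0566 and 0.0826. A gene changed in one comparison and not in another was not tested for a difference between comparisons. Of the 28 lists 10, 12 and 14 were called in the 3 comparisons in the order given, 0 of them with an estimated correlation. With that correlation 3, 1 and 2 lists had an unadjusted p under 0.05, while fry called 2, 0 and 7.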

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

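The test of library depth below was chosen after the shares were seen, while the Mup test and its bounds were written before its result was seen. A pair of read classes outside the gene counts stood above their controls in every library, which marked them for a closer look. Reads aligned to several places made up 15.3 ± 0.714% of the HFD_HDCA files (SD, n = 3, lowest 14.5%) against 13.6 ± 0.356% of the HFD files (SD, n = 3, highest 13.96%). Reads ambiguous between genes made up 1.14 ± 0.0910% against 0.880 ± 0.0865% (SD, n = 3 each).

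Both classes were higher still in ND, at 17.9% and 1.53%, so the pattern is a fall with HFD and a partial return with HDCA. A share that rises with library depth is argued against as the cause. The deepest HFD file, HFD 2, held more reads than the shallowest ND file, ND 3. Its share of multiply aligned reads was nonetheless 6.17 points lower (a difference of -6.17). These files had the lowest and highest shares of all files, at 13.3 and 19.4%, so the size of that difference is an extreme. Depth acting in another way was not tested. Reads shared between Mup paralogs are a candidate explanation. The Mup fragments estimated from the FPKM tables and not counted uniquely fell by 4.49 points from ND to HFD. This was 103% of the fall of 4.35 points in multiply aligned reads. The estimate took 925 bases, the median length of protein-coding Mup transcripts, for every Mup gene. FPKM refers to mapped fragments and the unique share to all reads in a file, so the 103% is approximate. The same quantity rose by 2.66 points with HDCA against 1.70 points for multiply aligned reads. Either other reads moved the other way or the estimate was inexact. By this estimate Mup genes held 8.80 ± 1.74, 4.003 ± 0.453 and 7.59 ± 1.73% of fragments in ND, HFD and HFD_HDCA (SD, n = 3 each). Single members such as Mup7 and Mup21 passed in a comparison. How the shared reads divide among the paralogs stays open.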

How the results depend on the processing

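All alternatives were planned except the joint removal of HFD 1 and HFD_HDCA 1 and the FPKM count of opposed genes, which were chosen after seeing the data. In the order HFD vs ND, HFD_HDCA vs HFD, HFD_HDCA vs ND, the counts of changed genes (120, 428, 815) became 366, 1040 and 1321 with DESeq2 and 229, 1020 and 1673 at an adjusted p under 0.1. Requiring 2-fold left 166 and 295 in the last pair, unfiltered FPKM gave 272 and 526, and a fit of 6 libraries gave 134 for HFD_HDCA vs HFD. Without HFD 1 and HFD_HDCA 1 together the first counts were 576 and 977. With the replicate number as a block they were 82, 328 and 715. In that fit the PPARA (0.0137) and bile acid (0.0447) lists were called for HFD vs ND and the fibrosis list was not for HFD_HDCA vs HFD (0.0657), and no other list call changed. Libraries with the same number correlated best with each other in 2 of 9 pairs, with correlations of deviations from -0.149 to 0.153. Both pairs were of number 1, ND 1 with HFD 1 (0.0983) and ND 1 with HFD_HDCA 1 (0.153). The number was not taken as a pairing, although something shared by the libraries numbered 1 cannot be excluded. With single libraries left out the counts of changed genes ran from 32 to 226, 127 to 672 and 196 to 1213. A lone remaining library never occurred, as each group kept at least 2. FPKM with its filter called 108 genes up and 66 down for HFD vs ND, against 60 and 60. It called 143 genes up and 381 down for HFD_HDCA vs HFD, a different balance from 210 and 218. These counts come from log2(FPKM + 1), where the median log2 fold change of all genes was 0.0911 and -0.0834 in the first pair of comparisons. With 0.1 as the pseudocount it was 0.110 and -0.105. Each gene was tested against 0, so this shift was not taken out of the balance. The 35 opposed genes became 17 in the fit of 6 libraries, 94 with DESeq2, 55 with FPKM, 179 without both libraries and 7 to 77 without single ones. Called lists (10, 12, 14) became 0, 0 and 0 with an estimated correlation and 2, 0 and 7 with fry, and with single libraries left out 9 to 13, 10 to 16 and 14 to 17. Apart from thresholds and numbers of libraries, the cause of these differences was not tested.

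Lists past the threshold in the opposite direction to their uncalled result were few. For HFD vs ND the macrophage list was higher without HFD 2 (0.00767), within 0.00763 to 0.978 over single libraries. For HFD_HDCA vs HFD endothelial genes were lower without HFD 2 (0.0470, range 0.0128 to 0.976) and cholesterol synthesis higher without HFD 3 (0.00349, range to 0.727). In that comparison acute phase (0.0413) and cholangiocyte (0.0450) genes were lower without both libraries that stood apart, and the cause was not tested. A sign that differed while neither value passed was counted as no change. No named gene changed sign past the threshold under any alternative run. Of 405 results for named genes, DESeq2 lost 0 calls and gained 66 among 399 it tested, the block lost 35 and gained 9, and single libraries lost 14 to 70. Small changes were mostly missed in the self-test, where 6 to 24% of planted 1.5-fold changes were recovered.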

Other observations

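The Txnip and Gm15441 values, the glycogen genes and the tests of sample sex, of time since feeding and of the libraries that stood apart were chosen after values were seen, whereas the splits and the paralog test of the sex-biased genes were written beforehand. Gbe1, encoding the glycogen branching enzyme, rose with HFD by 0.88 on the log2 scale and fell with HDCA by 1.42 (adjusted p = 0.00283). Pygl, liver glycogen phosphorylase, fell from 650.5 ± 163 to 339 ± 37.1 CPM and the glucose transporter gene Slc2a2 from 309 ± 34.4 to 151 ± 19.2 (SD, n = 3 each, adjusted p = 0.0278 and 0.0140). These are single genes, and the glucose list was not called (adjusted p = 0.115). Mid1ip1 and Acot11, a lipogenic cofactor and a thioesterase gene, rose with HFD by 1.20 and 0.85 on the log2 scale and fell with HDCA by 1.76 and 1.67.

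Gm15441, a long noncoding RNA on chromosome 3 from 96555768 to 96566801, overlaps Txnip, whose product inhibits thioredoxin, from 96557957 to 96561857. With HDCA Gm15441 stood at 6.42, 78.8 and 68.8 CPM, against 0.417 to 0.650 in the HFD libraries, a log2 fold change of 6.51 ± 1.09 (SE, n = 3 each, adjusted p = 0.0228 by edgeR). Txnip was higher by 1.68 ± 0.41 (SE) without passing (adjusted p = 0.0627). HFD_HDCA 1, low for Gm15441, was the library with the lowest PPARA score of its group and with S100a8 at 4.91 CPM against 0.755 and 0.481. Adipoq, an adipocyte gene, had 29 reads in HFD 2 and at most 3 in any other library.

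Male-biased genes were lower and female-biased genes higher in HFD as lists (7 of 19 fell, 5 of 13 rose, adjusted p = 0.141 for each with an estimated correlation). Mislabelled or mixed-sex samples are argued against, since the lowest sum of 4 Y-linked genes among HFD libraries was 101% of the ND mean and Xist had 0 reads in all 3. Reads shared between paralogs cannot be told apart from a real shift. The 8 male-biased genes outside the Mup, Cyp, Serpina1, Ugt2b and Gst families, some with paralogs of their own, had a median log2 fold change of -0.91, and 7 were negative. Its standard error of 0.70 reflects the spread between genes and not between libraries, so the test cannot decide. The FPKM tables called 7 male-biased genes lower and 0 higher, and 6 female-biased genes higher and 3 lower. How they divide shared reads was not stated, so these counts do not settle it. An effect of the diet may account for the pattern as a hypothesis, and hormone levels were not measured.

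Fatty acid synthesis genes were lower and PPARA targets higher with HDCA, with a difference of 2.53 between the lists' median log2 fold changes (5 of 23 fell, 6 of 25 rose, adjusted p = 0.531 for each with an estimated correlation). The difference did not rest on either library that stood apart, being 2.78 without HFD 1 and 2.82 without HFD_HDCA 1. HFD 1 had the lowest synthesis score of its group (-0.11) and HFD_HDCA 1 the lowest PPARA score (0.26). This test could therefore hardly have gone the other way. The difference was not recomputed without HFD 3, whose synthesis score was the highest at 1.41. A longer time since feeding in the HFD_HDCA livers stays open. The 8 genes raised by fasting outside the PPARA list had a median of -0.0977, with 4 up and 4 down. Its standard error of 0.351 reflects the spread between genes and not between livers, so the test cannot decide. The labels give a fed state for all livers. The direction is consistent with the PPARα activation named in the series title, which remains a hypothesis here because a difference in feeding could give part of it.

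With 3 libraries against 3 there are 10 splits, too few for a share under 0.1, and in each comparison 1 of the 10, the real one, gave as many genes. The real counts were 120, 428 and 815, and the highest of the other splits gave 3, 2 and 0. Each of the other splits mixes both diets on each side, so a diet difference widens their spread and lowers their counts.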
